A study of Mus musculus with 19 samples.

How the data were processed

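Transcript levels of bone marrow monocytes were taken from 1 table of 5 bulk RNA-seq libraries deposited by the authors, 3 with and 2 without G-CSF, all wild type per the labels. The values were deposited as FPKM, fragments per kilobase of gene length scaled to library size, with 1 column per library. The genome build was mm10 per the submitters' processing notes. Those notes name only Cell Ranger 5.0.1, a tool for single-cell data, and the protocol attached to the bulk labels describes skin cells, so the aligner, the counter, the annotation release, the strandedness and the sorting of the monocytes were not given in the sources used here. The 14 skin samples were not analysed here. Every column belonged to 1 labelled sample.

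The table held 33559 rows, 20 of them with a repeated symbol, and 89.6% of rows matched 1 gene of GENCODE M21 (GRCm38) by symbol. Within a library, FPKM times the exon length of that annotation was a whole multiple of 1 step, within 0.001 reads, in all 5 libraries for 94.3% of the matched rows, which gave the number of reads behind a value. Because rows without a match are left out, the sums are lower bounds of depth. They came to 5981813 reads in control replicate 1, 2923782 in control replicate 2, and 6988613, 6952829 and 5911053 in G-CSF replicates 1, 2 and 3. The totals used by the authors as divisors followed median-of-ratios size factors of these reads to within 2.64%, so the deposited FPKM already carried a scaling between libraries. Column sums were not comparable, because FPKM of short RNAs reached 1551643 in 1 row, the microRNA gene Gm55118, in control replicate 2. Symbols newer than GENCODE M21 occurred in the table, so coordinates, given 1-based on GRCm38, are those of the symbol in GENCODE M21 and not from the authors' annotation.

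Groups were taken from the labels. Genes with an FPKM of at least 1 in at least 2 libraries were kept (16791), and log2(FPKM + 1) was tested with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). The pseudocount of 1 understates the fold change of low genes. There were 3 residual degrees of freedom. Lists of genes (45, of which 41 had at least 5 tested members) were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. Camera compares a list with all other genes, and fry tests whether its members move on balance in 1 direction. Older symbols in the lists were matched through RefSeq synonyms with a single match.

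The test, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Csf3r, Cxcr2, Cxcr4, Ly6c2, Ccr2, Csf1r, Cx3cr1 and Ly6g in any case. It further named the 10 genes with the largest and the 10 with the smallest log2 fold change among those called with no overlap between groups, and where fewer passed, those with the smallest unadjusted p, said not to have passed. Symbols made of Gm and digits or ending in Rik, immunoglobulin and T cell receptor segments, microRNAs and pseudogenes named -ps were left out. From each list described, up to 4 members with the smallest p and the member with the highest level were named, and some genes that fall under the rule are not reported here.

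The tests were checked on simulated data with the means of the 16791 genes, 200 of which were changed. With the observed spread, 62% of genes changed by 2 on the log2 scale and 98% of those changed by 4 were recovered, with 10 false calls among 16591 unchanged genes, and 0 of 45 random lists were called. Genes were drawn independently, with the same spread in every library. The check therefore could not show false list calls that come from correlation among members, estimated at 0.356 for the inflammatory list in the real data. Replicates were compared before averaging: chi-square over degrees of freedom of the recovered reads was 115 between the controls and 7.88 to 46.5 between G-CSF libraries, so no pair agreed within sampling noise.

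The alternatives tried were other pseudocounts (0.1 and 5), no filter and a minimum FPKM of 5, TPM rescaling, quantile normalization, median centring, limma without trend or with a robust fit, the replicate number as a block, each library left out in turn, and a minimum absolute log2 fold change of 1. After the data were seen, protein-coding genes only, voom on the recovered reads, and both of these without control replicate 2 were added. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.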

Results

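The series comprised 19 mouse samples. Bone marrow monocytes, precursors of many tissue macrophages, were profiled by bulk RNA-seq in 5 libraries from wild-type mice. G-CSF, the cytokine that drives granulocyte production and is sensed through the receptor encoded by Csf3r, had been given to the cells or animals of 3 libraries (G-CSF replicates 1 to 3), and 2 libraries had no treatment (control replicates 1 and 2). The labels state neither the dose nor whether treatment was in vivo or in culture. The other 14 samples, single-cell libraries of wild-type and Cxcr2 knockout skin, were not analysed here, so no knockout comparison was made. The deposited table gave FPKM for 33559 genes, of which 17924 were protein-coding. Reads recovered from the FPKM steps, a lower bound of depth, numbered 5981813 and 2923782 in control replicates 1 and 2, and 6988613, 6952829 and 5911053 in G-CSF replicates 1, 2 and 3. The labels do not say whether replicates came from separate animals or cultures, so p-values measure the spread between these samples only, which may be technical.

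The single comparison asked which transcripts differed between monocytes with and without G-CSF. Socs3, a feedback inhibitor of STAT3 signalling induced by cytokine receptors, rose from 1.77 ± 0.183 FPKM (SD, n = 2) without G-CSF to 55.4 ± 6.54 FPKM (SD, n = 3) with it. Its log2 fold change was 4.34 ± 0.24 (SE) on the log2(FPKM + 1) scale, with a limma adjusted p of 0.0454. Socs3 lies on chromosome 11, from 117966079 to 117970047 on the minus strand of GRCm38 (ENSMUSG00000053113). Socs3 was the only one of 16791 genes tested that was called higher. It did not pass with a pseudocount of 5, no filter, TPM rescaling, quantile normalization or median centring (adjusted p from 0.0519 to 1.00), nor without control replicate 2 (adjusted p = 0.156), G-CSF replicate 1 (0.399), G-CSF replicate 2 (0.148) or G-CSF replicate 3 (0.368). In these settings the log2 fold change of Socs3 was 3.15 with a pseudocount of 5 and 4.26 to 4.43 in the others. By limma 0 genes were called lower, while 1327 genes were higher and 800 lower at an unadjusted p under 0.05. These unadjusted counts fell to 73 and 61 with TPM rescaling, 524 and 332 without G-CSF replicate 1 and 568 and 374 without G-CSF replicate 3. With no filter they were 1467 and 1427, and with quantile normalization 989 and 977, so the excess of higher genes was nearly gone in both. They rose to 4483 and 3125 without control replicate 1. Voom on recovered reads, added after the data were seen, called 8 genes higher and 2 lower. TPM rescaling divides each library by its column sum, 392646 in control replicate 1 and 3299131 in control replicate 2. Those sums were not comparable, so the loss of Socs3 and the drop in counts under TPM rescaling cannot be read as a test of the G-CSF difference.

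The other 9 genes with a positive log2 fold change that were named by rule, in order of p, were higher in all 3 G-CSF libraries than in both controls, and none passed the adjustment over all genes. Of all 16791 genes tested, 32.0% had no overlap between the groups in either direction, against 20% by chance. For genes picked by small p, such separation therefore adds little. Ifitm1, an interferon-inducible membrane protein, measured 219.7 ± 73.2 FPKM (SD, n = 3) with G-CSF against 4.14 ± 0.262 FPKM (SD, n = 2) without (limma adjusted p = 0.0525). Saa3, an acute-phase serum amyloid A protein, had the largest log2 fold change of the genes named, 6.80 ± 0.69 (SE), with 328, 88.0 and 359 FPKM in the G-CSF libraries and 0.454 and 1.66 FPKM in the controls (limma adjusted p = 0.107). The cystatin Stfa2 had a log2 fold change of 3.79 ± 0.28 (SE), and the chemokine-like peptide Prok2 had 3.11 ± 0.23 (SE), both with a limma adjusted p of 0.0598. For the protease inhibitor Spint1 it was 2.98 ± 0.25 (SE), for the matrix proteoglycan Vcan 2.86 ± 0.29, for Igfbp6 3.14 ± 0.31, for the endothelin receptor Ednrb 3.79 ± 0.38 and for Ly6i 3.81 ± 0.40 (adjusted p between 0.0693 and 0.11). Stfa2 and Ly6i belong to families of near-identical copies, so their values are uncertain. Fold changes of low genes depended on the pseudocount: with 5 in place of 1, the log2 fold change of Stfa2 was 1.93. When protein-coding genes alone were tested, an alternative chosen after the data were seen, 30 of 10524 genes were called higher and 3 lower. All of the genes named in this paragraph were among the 30, with adjusted p between 0.00938 and 0.0269.

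**Figure D1:**
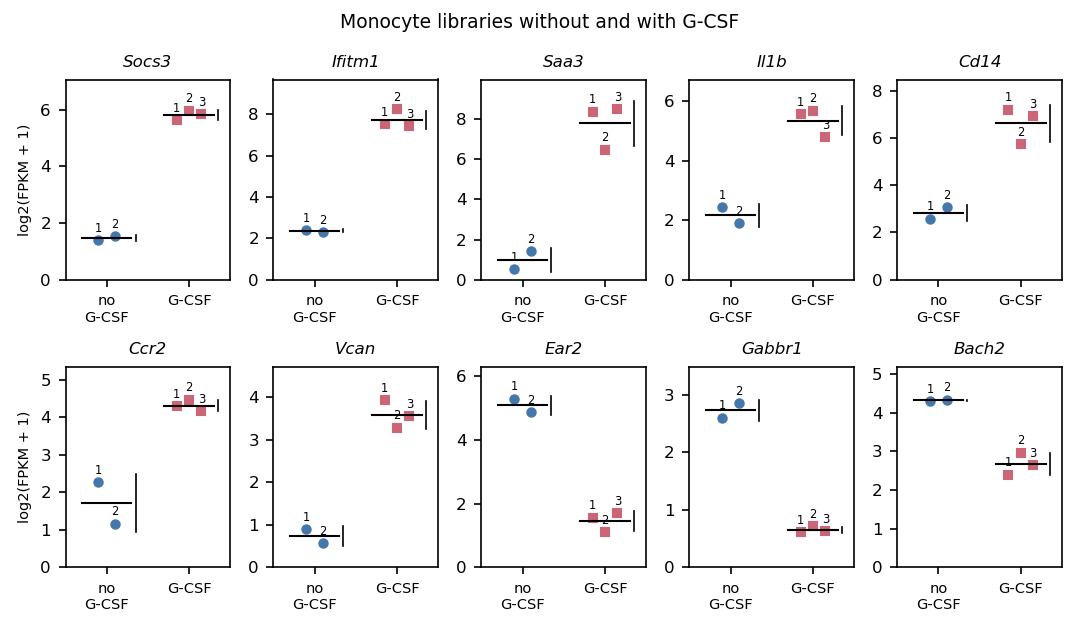
Expression of 10 named genes as log2(FPKM + 1) in each library, with blue circles for the 2 libraries without G-CSF and red squares for the 3 with G-CSF. Digits are replicate numbers, horizontal lines are group means and vertical bars are 1 SD. The groups do not overlap for any of the 10, as for 32.0% of all genes tested, and only Socs3 passed the test over all genes.

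Among the lower genes, Ear2, an eosinophil-associated ribonuclease, had the smallest p. It measured 33.5 ± 7.04 FPKM (SD, n = 2) without G-CSF and 1.77 ± 0.563 FPKM (SD, n = 3) with G-CSF, a log2 fold change of -3.64 ± 0.29 (SE) that did not pass (limma adjusted p = 0.0673). Ear2 has near-identical paralogs, so reads may have been shared among them. Gabbr1, a GABA-B receptor subunit, had a log2 fold change of -2.08 ± 0.23 (SE; limma adjusted p = 0.131). Both were called lower when protein-coding genes alone were tested. The B cell transcription factors Bach2 and Pax5 had log2 fold changes of -1.65 ± 0.26 and -1.47 ± 0.23 (SE), and the receptor tyrosine kinase Axl, a macrophage gene, had -2.76 ± 0.48 (SE). The remaining 5 of the 10 lower genes named by rule, Adpgk, Robo3, Cplx2, Carns1 and Smim5, had log2 fold changes between -2.32 and -1.35. None of these 8 genes passed (limma adjusted p between 0.199 and 0.212).

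Gene lists fixed before the data were examined were then compared with all other genes. Of 41 lists with at least 5 tested members, 19 were higher and 5 lower with G-CSF by camera with a preset correlation. With an estimated correlation 0 lists passed, the smallest adjusted p being 0.305, and fry, which does not compare a list with other genes, called 11 higher and 1 lower. Camera with an estimated correlation also rests on the 3 residual degrees of freedom, so few lists could pass. The cholesterol synthesis list, with an estimated correlation of -0.040, went from an unadjusted camera p of 3.04e-04 to 0.0285. The lost calls therefore do not measure correlation among members alone. Single-gene counts below are adjusted over the list alone. Over all genes tested, Socs3 was the only member of any list to pass.

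Inflammatory cytokines and NF-kB targets were higher together. All 19 tested members had a positive log2 fold change, 14 rose when adjusted over the list alone, 0 fell and 5 did not pass, with a median of 1.87 (camera adjusted p = 7.07e-12; adjusted p = 0.305 with an estimated correlation). Il1b, encoding interleukin-1 beta, measured 41.3 ± 12.6 FPKM (SD, n = 3) with G-CSF and 3.56 ± 1.19 FPKM (SD, n = 2) without. The macrophage growth factor gene Csf1 measured 26.6 ± 5.04 against 3.94 ± 0.788 FPKM, and the chemokine genes Cxcl2 and Ccl7 had log2 fold changes of 2.50 ± 0.36 and 2.16 ± 0.26 (SE). Tnfaip2, the member with the highest level, measured 115.3, 79.1 and 115.9 FPKM with G-CSF and 54.5 and 79.3 FPKM without. Pattern recognition receptors moved the same way: 22 of 24 members were positive, 9 rose when adjusted over the list alone, 0 fell and the median was 1.04 (camera adjusted p = 8.00e-08; adjusted p = 0.305 with an estimated correlation). Its leading members were the lipopolysaccharide co-receptor Cd14 at 106 ± 48.2 against 6.15 ± 1.67 FPKM, Tlr2 at 54.8 ± 12.1 against 8.65 ± 4.92 FPKM, and the C-type lectins Clec4e and Clec4n with log2 fold changes of 3.31 ± 0.56 and 2.84 ± 0.52 (SE). Clec4d headed the list by level, at 159.9, 68.4 and 132.6 FPKM with G-CSF and 51.1 and 12.4 FPKM without. Its log2 fold change was 1.13 without control replicate 2 and 3.09 without control replicate 1.

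Targets of G-CSF receptor and STAT3 signalling were higher, with 16 of 20 members positive, 6 that rose when adjusted over the list alone, 0 that fell and a median of 0.85 (camera adjusted p = 2.18e-04; adjusted p = 0.305 with an estimated correlation). Their median was 0.417 against control replicate 1 alone. Besides Socs3, they included Junb at 106 ± 5.73 against 26.6 ± 5.48 FPKM, Bcl3 at 40.1 ± 6.05 against 9.35 ± 2.60 FPKM, and the secreted glycoprotein Lrg1 at 221 ± 64.2 against 53.3 ± 2.31 FPKM. Cebpb headed this list by level at 395, 249 and 423 FPKM with G-CSF and 55.0 and 228 FPKM without. Csf3r itself did not pass, with a log2 fold change of 0.80 ± 0.76 (SE; limma adjusted p = 0.658). The value was -0.358 without control replicate 2 and 1.95 without control replicate 1. Type I interferon response genes were higher, with 23 of 24 members positive, 10 that rose when adjusted over the list alone, 0 that fell and a median of 0.92 (camera adjusted p = 8.00e-08; adjusted p = 0.305 with an estimated correlation). The 2'-5' oligoadenylate synthetase gene Oas2 measured 5.52 ± 0.273 against 1.07 ± 0.221 FPKM, and the ubiquitin-like modifier Isg15 8.91 ± 1.90 against 1.61 ± 1.20 FPKM. The immediate early and dissociation stress list had 19 of 21 members positive and 7 that rose when adjusted over the list alone, with a median of 0.81 (camera adjusted p = 2.35e-06; adjusted p = 0.305 with an estimated correlation). Nr4a1 measured 9.10 ± 2.90 against 2.14 ± 0.23 FPKM and Egr1 5.63 ± 1.39 against 1.46 ± 0.244 FPKM, whereas Jund, the member with the highest level, ranged from 61.6 to 523 FPKM between the controls.

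Classical monocyte genes were higher, with 19 of 21 members positive, 9 that rose when adjusted over the list alone, 0 that fell and a median of 1.00 (camera adjusted p = 4.58e-07; adjusted p = 0.305 with an estimated correlation). Their median was 1.799 against control replicate 2 alone. Ccr2, the chemokine receptor that directs monocytes out of the marrow, measured 18.8, 21.2 and 17.0 FPKM with G-CSF and 3.82 and 1.24 FPKM without (log2 fold change 2.60 ± 0.37, SE), and did not pass over all genes (limma adjusted p = 0.179). The coagulation factor gene F13a1 measured 30.4 ± 4.30 against 5.33 ± 3.72 FPKM. Ly6c2, the classical monocyte surface antigen, and Csf1r, the receptor for macrophage colony-stimulating factor, had log2 fold changes of 1.28 ± 0.48 and 1.09 ± 0.33 (SE), neither of which passed (limma adjusted p = 0.375 and 0.325). Without control replicate 1, which leaves control replicate 2 as the lone control, the log2 fold changes were 1.998 and 1.17. Without control replicate 2 they were 0.561 and 1.01. Lyz2, the list's most abundant transcript, had a log2 fold change of 0.93 ± 0.77 (SE; limma adjusted p = 0.613). The value was 0.171 without control replicate 2 and 1.68 without control replicate 1. For the non-classical marker Cx3cr1 the log2 fold change was -0.05 ± 0.31 (SE; limma adjusted p = 0.952), positive without control replicate 1 (0.191) or G-CSF replicate 2 (0.157), and its list did not pass (camera adjusted p = 0.124).

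**Figure D2:**
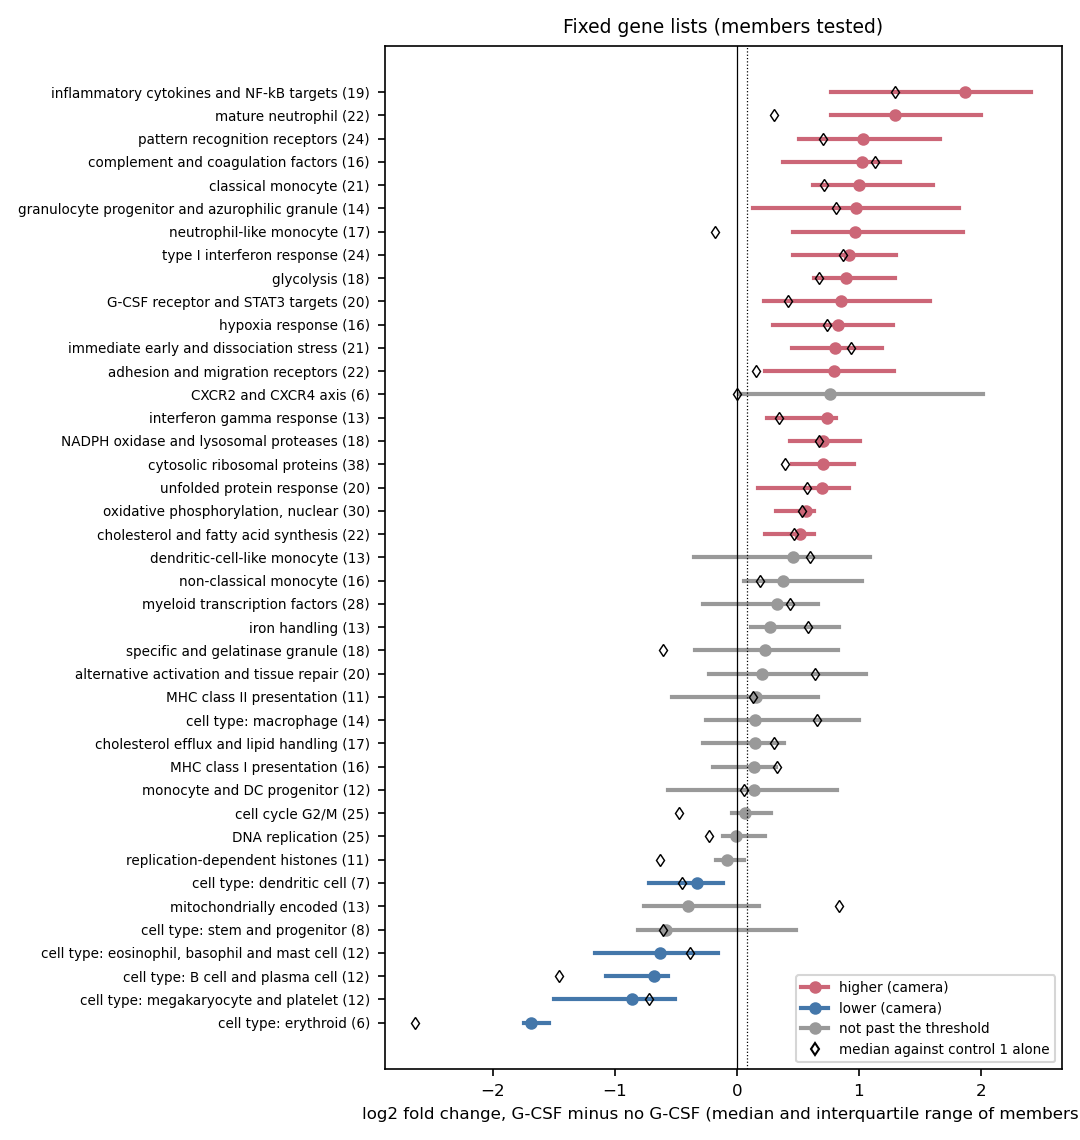
Median log2 fold change on the log2(FPKM + 1) scale, G-CSF minus no G-CSF, for each of the 41 gene lists tested, with bars spanning the interquartile range of members and the number of members in parentheses. Red and blue mark the 19 lists higher and 5 lower by camera with a preset correlation, open diamonds the median against control replicate 1 alone and the dotted line the median of all genes (0.08); the inflammatory list lies highest at 1.87 and the erythroid list lowest at -1.69.

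The mature neutrophil list was higher (19 of 22 members positive, 9 that rose when adjusted over the list alone, median 1.29, camera adjusted p = 6.35e-05; adjusted p = 0.434 with an estimated correlation), and this call was lost without control replicate 2 (camera adjusted p = 0.196). Its median was 0.303 against control replicate 1 alone and 2.31 against control replicate 2 alone. The 1 member that fell when adjusted over the list alone was G0s2, named after its values were seen. Among the members that rose, Il1b, Cxcl2, Clec4d and Lrg1 also belong to lists described above, so the list calls are not independent. Azurophilic granule and granulocyte progenitor genes were also higher (11 of 14 positive, 7 that rose and 1 that fell when adjusted over the list alone, camera adjusted p = 0.00584; adjusted p = 0.434 with an estimated correlation). They were led by the serine protease genes Prtn3 at 168 ± 30.1 against 38.8 ± 2.87 FPKM and Ctsg at 78.5 ± 9.66 against 16.3 ± 9.29 FPKM, while the member that fell, the transcription factor gene Gfi1, measured 4.92 ± 1.56 against 13.4 ± 2.93 FPKM. The list's call was lost without G-CSF replicate 2 (camera adjusted p = 0.0635), with a minimum FPKM of 5 (camera adjusted p = 0.0525), and with protein-coding genes only without control replicate 2 (camera adjusted p = 0.106). Specific and gelatinase granule genes did not pass (12 of 18 positive, camera adjusted p = 0.929), and the list was called lower without control replicate 2 (camera adjusted p = 0.00223) and higher without control replicate 1 (camera adjusted p = 0.0113). In it, the antimicrobial peptide gene Camp measured 86.1, 208 and 66.8 FPKM with G-CSF and 1187 and 402 FPKM without, and Ngp, the most abundant member, measured 1577, 1846 and 1534 FPKM against 3299 and 749 FPKM. Neutrophil-like monocyte genes were called higher (14 of 17 positive, 4 that rose, namely Saa3, Prtn3, Elane and Mpo, and Camp that fell when adjusted over the list alone, camera adjusted p = 0.00606; adjusted p = 0.56 with an estimated correlation), a call lost without control replicate 2 (camera adjusted p = 0.906) and with a minimum FPKM of 5 (camera adjusted p = 0.0584). Against control replicate 1 alone the median of this list was -0.18, and without control replicate 2 its direction turned to lower, not past the threshold, with protein-coding genes only (camera adjusted p = 0.859) and with voom (camera adjusted p = 0.973).

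Cxcr2, the chemokine receptor knocked out in 8 of the 14 skin samples of the series, was detected in every monocyte library. These bulk libraries also held transcripts of the neutrophil antigen Ly6g, at 9.88 to 54.9 FPKM. Control replicate 1 exceeded control replicate 2 by 4.99-fold for Cxcr2 and 3.52-fold for Ly6g, so Cxcr2 reads cannot be assigned to monocytes alone. Cxcr2 measured 61.6, 119 and 53.2 FPKM with G-CSF and 55.7 and 11.2 FPKM without, a log2 fold change of 1.50 ± 0.72 (SE) that did not pass (limma adjusted p = 0.442). The value was 0.386 without control replicate 2 and 2.61 without control replicate 1, each a fit with 1 control left. Cxcr4, the marrow retention receptor, had a log2 fold change of 0.03 ± 0.63 (SE; limma adjusted p = 0.984). The value was -1.045 without control replicate 2, 1.106 without control replicate 1 and -0.0534 without G-CSF replicate 2. It also turned negative under quantile normalization (-0.167) and median centring (-0.0215). Ly6g, a neutrophil surface antigen, had a log2 fold change of -0.97 ± 0.63 (SE; limma adjusted p = 0.525). The value was -1.85 without control replicate 2 and -0.099 without control replicate 1. The list of the CXCR2 and CXCR4 axis did not pass (5 of 6 members positive, camera adjusted p = 0.127) and was called higher under TPM rescaling (camera adjusted p = 0.00385).

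**Figure D3:**
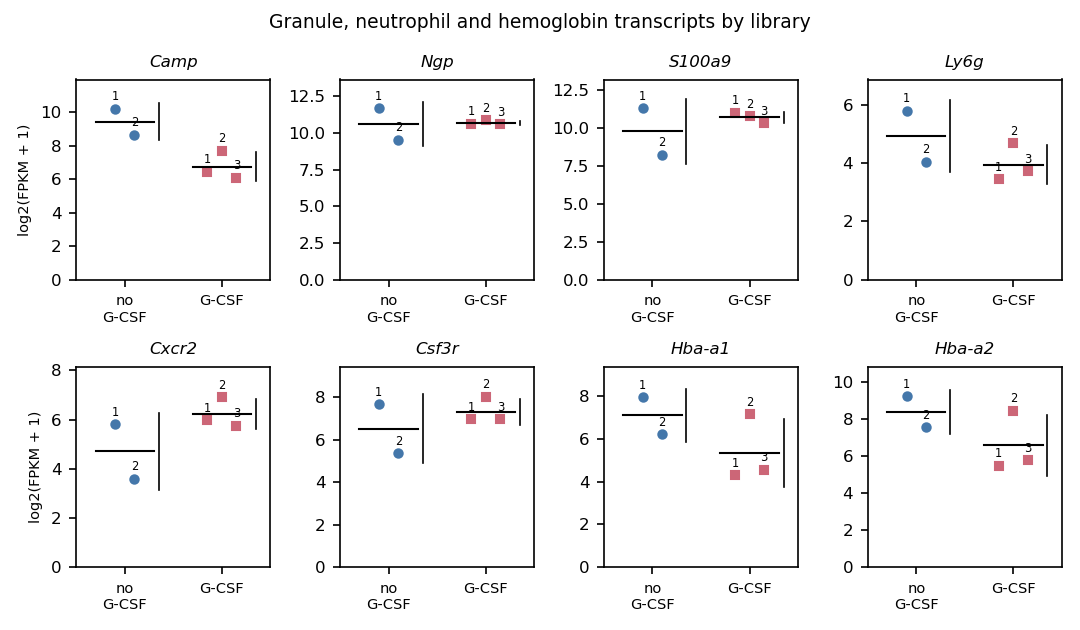
Expression of 8 granule, neutrophil and hemoglobin transcripts as log2(FPKM + 1) in each library, with blue circles for the 2 libraries without G-CSF and red squares for the 3 with G-CSF. Digits are replicate numbers, horizontal lines are group means and vertical bars are 1 SD; control replicate 1 exceeds control replicate 2 for all 8, and G-CSF replicate 2 exceeds G-CSF replicates 1 and 3 for 7 of them, S100a9 excepted.

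Several lists of energy metabolism and protein synthesis genes were also higher. The glycolysis list had 16 of 18 members positive, 5 that rose when adjusted over the list alone (Slc2a1, Pfkp, Tpi1, Slc16a3 and, named after its values were seen, Pfkl) and a median of 0.90 (camera adjusted p = 6.44e-06; adjusted p = 0.305 with an estimated correlation). The glucose transporter gene Slc2a1 measured 42.1 ± 11.3 against 11.2 ± 1.94 FPKM, and Pkm, encoding pyruvate kinase, 419 ± 18.0 against 234 ± 38.4 FPKM. Cytosolic ribosomal protein genes were positive for 37 of 38 members with a median of 0.70, and 0 members passed when adjusted over the list alone (camera adjusted p = 2.17e-06; adjusted p = 0.394 with an estimated correlation). Their median was 0.396 against control replicate 1 alone and 1.07 against control replicate 2 alone. The lists for hypoxia, nuclear oxidative phosphorylation, cholesterol synthesis, lysosomal proteases, unfolded protein response, adhesion receptors and interferon gamma response had medians between 0.51 and 0.83 (camera adjusted p between 2.18e-04 and 0.00932; adjusted p between 0.305 and 0.434 with an estimated correlation). Without control replicate 2, the calls for adhesion receptors (camera adjusted p = 0.225) and interferon gamma response (camera adjusted p = 0.14) were lost. Their medians against control replicate 1 alone were 0.154 and 0.348. Without control replicate 1, those for oxidative phosphorylation (0.180) and the unfolded protein response (0.149) were lost, the latter also with a minimum FPKM of 5 (0.0525).

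Marker lists of 5 other marrow cell types were lower with G-CSF, while those of macrophages (camera adjusted p = 0.929) and of stem and progenitor cells (camera adjusted p = 0.27) did not pass. Megakaryocyte and platelet genes had 10 of 12 members negative, 4 that fell when adjusted over the list alone (Itga2b, Gp9 and Itgb3 among them) and a median of -0.86 (camera adjusted p = 4.15e-06; adjusted p = 0.31 with an estimated correlation). The platelet integrin gene Itga2b measured 13.7 ± 0.583 FPKM with G-CSF against 54.7 ± 29.5 FPKM without. Pf4, the list's most abundant member, measured 488, 313 and 459 FPKM with G-CSF and 190 and 638 FPKM without. Its log2 fold change was 1.11 without control replicate 2 and -0.628 without control replicate 1. B cell and plasma cell genes were negative for all 12 members, with 2 that fell when adjusted over the list alone (Pax5 among them) and a median of -0.68 (camera adjusted p = 6.91e-06; adjusted p = 0.342 with an estimated correlation). Ighm, encoding the IgM heavy chain, measured 53.8, 70.0 and 69.5 FPKM with G-CSF and 191 and 69.0 FPKM without, so the groups overlapped. Its log2 fold change was -0.107 without control replicate 1 and -1.56 without control replicate 2. Eosinophil, basophil and mast cell genes were negative for 10 of 12 members, with 2 that fell when adjusted over the list alone, Ear2 and Prss34 (median -0.63, camera adjusted p = 2.18e-04; adjusted p = 0.305 with an estimated correlation), and the basophil protease gene Prss34 measured 51.2 ± 11.3 against 129.7 ± 17.9 FPKM. Dendritic cell genes (6 of 7 negative, median -0.33, camera adjusted p = 0.033; adjusted p = 0.31 with an estimated correlation) and erythroid genes (6 of 6 negative, median -1.69, camera adjusted p = 0.00246; adjusted p = 0.349 with an estimated correlation) were lower too. The B cell (camera adjusted p = 0.136), erythroid (0.201) and dendritic cell (0.479) calls were lost without control replicate 1, and the dendritic cell call without G-CSF replicate 2 (0.0523) and under TPM rescaling (0.0617). Against control replicates 1 and 2 alone the medians were -1.46 and -0.208 for B cell genes, -2.63 and -0.682 for erythroid genes and -0.449 and 0.0425 for dendritic cell genes. The median of eosinophil, basophil and mast cell genes was -0.383 against control replicate 1 alone. Erythroid transcripts varied within the groups as well: Hba-a2, an alpha globin gene with a near-identical copy, measured 43.4, 344 and 53.7 FPKM with G-CSF and 589 and 185 FPKM without.

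Complement and coagulation factors were higher (13 of 16 positive, 4 that rose when adjusted over the list alone, F10, F13a1 and C5ar1 among them, median 1.02, camera adjusted p = 3.60e-04; adjusted p = 0.342 with an estimated correlation), a call lost without control replicate 1 (camera adjusted p = 0.0661). The other 17 lists tested did not pass, with camera adjusted p between 0.124 and 0.991. Camera compares the mean test statistic of a list with that of all other genes. It gave a lower direction for MHC class I and class II presentation and the cell cycle although their medians were 0.14, 0.16 and 0.07, none past the threshold. The cell cycle list was called lower without control replicate 2 (camera adjusted p = 5.02e-06) and higher without control replicate 1 (camera adjusted p = 0.0352). Control replicate 2 stood apart from the other 4 libraries, with correlations across the 16791 genes of 0.78 to 0.82 against 0.88 to 0.97 among the others, where genes are not independent replicates. Without control replicate 1, which leaves control replicate 2 as the lone control, 2698 genes were called higher and 2002 lower.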

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

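The alternatives with protein-coding genes only and with voom were chosen after the data were seen. The main counts were 1 gene higher, 0 lower, 19 lists higher and 5 lower. The number of genes higher was 3 with a pseudocount of 0.1, 2 with a minimum FPKM of 5 and 2 without trend, and 0 with a pseudocount of 5, no filter, quantile normalization or median centring. TPM rescaling called 1 gene, which was not Socs3 (adjusted p = 1.00). With limma the number lower was 0 in all of these, against 800 genes at an unadjusted p under 0.05. At an unadjusted p under 0.05, quantile normalization gave 989 genes higher and 977 lower and TPM rescaling 73 and 61, against 1327 and 800 as deposited. Leaving out each library in turn gave 0 to 2698 genes higher, 0 to 2002 lower, 17 to 19 lists higher and 3 to 9 lower, the largest gene counts without control replicate 1 and 9 lists lower without control replicate 2. With 1 control left, that sample is assumed to vary like the G-CSF libraries. Protein-coding genes only gave 30 higher and 3 lower, and without control replicate 2 as well 113 higher, 53 lower and 9 lists lower. With both controls, the protein-coding setting tested 10524 genes in place of 16791. There the limma adjusted p of Socs3 went from 0.0454 to 0.00753, a larger drop than fewer tests alone give. Unadjusted p-values therefore changed in that fit as well. Voom on recovered reads gave 8 higher and 2 lower, and without control replicate 2 123 higher, 108 lower and 8 lists lower. Lists numbered 8 lower with no filter and 2 lower with a minimum FPKM of 5. With an estimated correlation 0 lists were higher and 0 lower, and by fry 11 were higher and 1 lower. TPM rescaling divides by column sums, which were not comparable, and camera with an estimated correlation also rests on the 3 residual degrees of freedom. The cause of the other shifts was not tested.

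Deviations from group means correlated at -0.07 and -0.23 across genes in the 2 same-numbered pairs and so gave no sign of pairing by replicate number. With 2 controls their deviations are mirror images of each other, so pairing cannot be excluded this way. With the number as a block, G-CSF replicate 3 was alone in its block and did not enter the log2 fold change. In that fit 0 genes were higher and 0 lower, with 20 lists higher and 4 lower. Socs3 (log2 fold change 4.33, adjusted p = 0.178) and the dendritic cell list (camera adjusted p = 0.0644) did not pass there, and the list of the CXCR2 and CXCR4 axis was called higher (camera adjusted p = 0.0191).

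For the 90 genes named, 1692 values were recomputed over 19 settings. Of these, 1482 kept direction and side of the threshold, 172 newly passed, 10 no longer passed (all Socs3) and 28 changed sign, none of them called in the main test. Most of the 90 genes newly passed without control replicate 1, which leaves control replicate 2 as the lone control, so the 172 are no measure of support. Leaving out each library in turn, log2 fold changes ranged from -0.358 to 1.95 for Csf3r, -1.045 to 1.106 for Cxcr4, -1.84 to 1.23 for Jund, -0.604 to 2.46 for S100a9, -1.002 to 1.136 for Ngp and -1.26 to 0.912 for C1qb. In these 6 genes the 2 extremes came without control replicate 2 and without control replicate 1. Testing protein-coding genes alone gives the same values by construction, since the choice of genes does not enter a gene's log2 fold change. Nor do the filters, limma without trend or the robust fit, so these settings could not reverse any of their share of the 1692 values. The ranges were -0.284 to 0.191 for Cx3cr1, -0.628 to 1.11 for Pf4 and -0.364 to 0.0425 for Wdfy4. Voom without control replicate 2 gave -0.369 for Csf3r, -1.059 for Cxcr4, -0.609 for S100a9, -1.005 for Ngp and 0.920 for C1qb. Cxcr4 was -0.167 and Ngp -0.383 under quantile normalization, Cxcr4 was -0.0215 under median centring, and Wdfy4 was 0.0566 and C1qb 0.0834 under TPM rescaling. The cause was not tested. Depth limits genes near an FPKM of 1 most in control replicate 2, at 2923782 recovered reads.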

Other observations

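The tests of the inflammatory list and of other splits of the libraries were chosen only after those results were seen.

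The coagulation factor gene F10 measured 132 ± 30.8 FPKM (SD, n = 3) with G-CSF against 19.5 ± 1.41 FPKM (SD, n = 2) without, and the complement receptor gene C5ar1 174 ± 26.5 against 67.1 ± 4.80 FPKM. Neither passed over all genes by limma (adjusted p = 0.147 and 0.259). C1qb, the most abundant member of the complement and coagulation list and also a macrophage marker, measured 422, 358 and 553 FPKM with G-CSF and 232 and 1045 FPKM without. The alternative activation and tissue repair list did not pass (13 of 20 members positive, camera adjusted p = 0.197) and was called higher without control replicate 2 (camera adjusted p = 0.00785). Lists with too few members for a test included stromal cells, of which Col1a1, a collagen gene, measured 0.703 ± 0.0797 against 11.1 ± 8.41 FPKM. Within the groups, Hba-a2 in G-CSF replicate 2 was 7.09 times the mean of G-CSF replicates 1 and 3, and in control replicate 1 it was 3.19 times control replicate 2. Of 508 olfactory and vomeronasal receptor genes 482 were above 0 in control replicate 2 and 71 to 137 in the other 4 libraries.

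Control replicate 2 correlated less with the G-CSF libraries than control replicate 1 did, at a mean r of 0.823 against 0.918 across 9968 protein-coding genes. Lower depth alone is argued against, since control replicate 1 thinned to the depth of control replicate 2 kept a mean r of 0.915. Reads spread evenly at the density of the receptor genes, 0.447 reads per kilobase, are argued against as the whole difference, because taking them off left 0.823. Such a density is small for the genes kept, and background that is uneven between genes was not tested. Removing a trend on GC content and transcript length gave 0.837, still below control replicate 1. A different animal, culture, sort or RNA quality stays open, and no biological explanation was tested.

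The inflammatory list may reflect G-CSF, and technical sources were weighed. Control replicate 2 as the only source is argued against, since 18 of 19 members were higher than in control replicate 1 alone. A scaling factor moves all genes of a library alike, and as deposited the median log2 fold change was 0.0846 for all genes and 1.87 for the list. That gap argues against scaling as the only source. The list's median stayed at 1.72 or more under TPM rescaling, quantile normalization and median centring, where the median of all genes was at most 0.119. TPM rescaling and median centring apply 1 factor per library, so they were bound to keep most of the gap and add little. A larger share of classical monocytes cannot be told apart, because the list's mean log2 fold change exceeded that of the other classical monocyte genes by 0.415, a gap that did not pass (permutation p = 0.193, two-sided, genes as units). Stress during cell handling stays open, as the immediate early list was higher too (camera adjusted p = 2.35e-06), with an adjusted p of 0.305 with an estimated correlation. Some immediate early genes are also targets of cytokine signalling.

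The 5 libraries can be split into 2 and 3 in 10 ways, too few for a share under 0.05. The real split called 1 gene, the highest of the other splits 0, and 1 of the 10 splits, the real one, gave as many.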
